A study of Homo sapiens with 4 samples.

How the data were processed

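RNA from 4 samples was profiled, SK-N-MC and TC-71 cells each without and with dox, 1 array per sample. The groups were read from the sample titles, and n is 1 per line and condition. Biotin-labelled material was prepared from total RNA and hybridised to human Clariom D arrays, per the labels' protocols. The authors normalized the 4 arrays with the SST-RMA algorithm in Affymetrix Expression Console 1.4, and the deposited values are log2 expression at the level of genes, per the series' design text. RMA is also named in the submitters' processing notes. RMA methods correct background, quantile normalize and summarise the probes of a feature, so the arrays are put on nearly the same distribution. Differences are on the log2 scale of that algorithm. The signal space transformation named in SST-RMA acts on that scale, so a fold is a fold of transformed signal. The genome build is not given in the sources used here, and no coordinates are reported. Scanner files, and with them background flags, scan dates and slide positions, were not used here, so no batch could be tested and no feature could be called absent.

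The deposited table held 24589 features and 4 columns of log2 values, with no missing value and 0 columns of other samples. No pair of arrays was a duplicate: at most 2 features had identical values in any pair. Arrays of a line correlated at 0.993 (SK-N-MC) and 0.995 (TC-71) over all features, and arrays of different lines at 0.948 to 0.953, so the shared cell line pairs the arrays. Features were named from a table of the platform's annotation. Of them, 23353 had 1 gene symbol, 264 had several and 972 had none there. Of 19972 single-symbol features with an Entrez ID, 19947 were found in the RefSeq gene table (GRCh38.p14), which changed 0 symbols. Only 1 symbol had more than 1 feature, and the feature with the highest mean was kept. Genes were kept when their mean over the 4 arrays was at or above the 40th percentile of all features' means (6.14 on the log2 scale), which left 13975 genes, of which 11460 are protein coding.

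Within a line, the difference is the array with dox minus the array without, with no test. Over both lines, limma 3.58.1 (R 4.3.3) was fitted with cell line and dox as terms (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). This fit has 1 residual degree of freedom, and its residual is the difference between the lines' responses. The fitted prior had 9.17 degrees of freedom and an SD of 0.199. Standard errors (SE) are moderated with this prior. They lean on the spread of all genes and are not the spread of a gene's own values. The line coefficient of the same fit compared the lines, with a further limit of 4-fold. The labels do not say that the cultures were independent beyond the cell line, so the limma p-values measure the spread between these arrays.

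There were 27 gene lists fixed before the data were examined, all with at least 5 measured members: IAP family and TNF receptor complex, non-canonical NF-kB pathway, TNF and NF-kB target genes, apoptosis regulators, p53 target genes, interferon-stimulated genes, MHC class I presentation, G1/S and G2/M genes, EWSR1-FLI1 activated genes, EWSR1-FLI1 repressed and mesenchymal genes, ATF4 genes, mitochondrially encoded transcripts, nuclear OXPHOS subunits, mitochondrial translation, glycolysis and hypoxia, ER chaperones, cholesterol synthesis, immediate-early and AP-1, neuronal differentiation, heat shock, replication-dependent histones, cytosolic ribosomal proteins, and leukocyte, epithelial, endothelial and fibroblast markers. In each line a list's median difference was placed among 10000 random lists of the same size matched on mean level in 10 bins. Over both lines, camera was run with a preset correlation of 0.01 and with an estimated correlation, adjusted over the 27 lists. With an estimated correlation 0 lists passed, for dox and for the line difference. The rotation test fry, run as a further value, called 0 lists for dox (smallest adjusted p 0.974) and 0 for the line difference (smallest adjusted p 0.230). With 1 residual degree of freedom the estimated correlation is itself poorly determined.

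Named genes followed a rule fixed before the data were examined: BIRC2, BIRC3, XIAP and CIAPIN1, the 12 genes higher and 12 lower in both lines by the smaller of the 2 differences, the 6 most increased and 6 most decreased in each line, the 4 largest opposite responses in each orientation, up to 4 members of each list by mean difference, and the 10 genes most different between the lines in each direction. Uncharacterised loci, small RNAs, pseudogenes and some gene families were counted and not named. HSPA5, DERL1, RIGI, EXO1 and TXNIP fall outside the rule and were chosen after their values were seen, as were the named members of an added DNA repair list. That list was written after BRCA1 and EXO1 had been seen and leaves them out, and the values of its members were seen only afterwards.

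The fit was tested on simulated data with 13975 genes, the real line means and noise drawn from the fitted prior. In these data 200 genes were changed, each by the same amount in both lines. For the comparison of dox with no dox over both lines, a mean of 76.05% of 2-fold and 99.8% of 4-fold changes was called over 20 simulations. The real responses of the lines were only weakly related (Pearson's r = 0.119), so these shares do not give the power of the fit on the real data. Of the calls, a mean of 17.4% were unchanged genes (range 0.794% to 34.6%), above the nominal 5%. Given the true prior, the share was 5.23%, so the excess comes from estimating the prior with 1 residual degree of freedom. In the same test, 100% of lists shifted by 0.5 lay above the central 95% of random lists, and 6% of unshifted lists lay outside it. The simulated genes varied independently of each other. Members of a real list can vary together, so these shares do not give the error rate of the percentiles of the real lists. Alternatives were quantile normalization, median centring, no filter, a filter on the highest array, averaging of features, another prior, other fold limits, list means and a fit without the cell line term.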

Results

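Gene expression was measured in SK-N-MC and TC-71, established cell lines derived from Ewing sarcoma, a tumour of bone and soft tissue driven by an EWSR1-ETS fusion. Both lines carried a doxycycline-inducible construct for re-expression of CIAP1. The name cIAP1 is the usual protein name for the product of BIRC2, a ubiquitin ligase of the inhibitor of apoptosis family that acts in TNF receptor and NF-kB signalling. Cells were seeded at 1000000 per flask and cultured for 96 h without doxycycline (dox) or with 1 µg/ml dox, refreshed after 48 h. RNA was hybridised to human Clariom D arrays. There was 1 array for each line and condition, 4 arrays in all, so a difference within a line has no replicate check. Dox p-values of single genes treat the lines as the repeats (2 arrays without and 2 with dox, cell line as a block). The camera p-values of gene lists set the genes of a list against the other genes and measure no replicate spread. Lines without the construct given dox were not part of the design, so differences are between cultures with and without dox. The 4 arrays had medians of 6.83, 6.81, 6.77 and 6.79 (log2) over 24589 features, and the number of arrays limits the precision.

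The first comparison asked whether the induced gene was higher with dox, which also checks the labels. It was, in both lines. BIRC2 (feature TC1100013088.hg.1) went from 12.19 to 14.98 on the log2 scale in SK-N-MC, a 6.93-fold difference, and from 10.57 to 11.95 in TC-71, a 2.60-fold difference. The mean log2 difference over the lines was 2.09 ± 0.29 (moderated SE of limma, n = 2 lines). Its p was the second lowest of 13975 genes, with an adjusted p of 0.153 (limma, Benjamini-Hochberg). The moderated SE is drawn towards the spread of all genes and is not the spread of the 2 lines, which differed by 2.79 and 1.38 with dox. The starting level was higher in SK-N-MC, where BIRC2 without dox already exceeded the level that TC-71 reached with dox. The related inhibitor XIAP differed by -0.14 in SK-N-MC and 0.03 in TC-71. CIAPIN1, whose name could be confused with the label, differed by -0.29 and -0.08. BIRC3, the closest relative of BIRC2 and part of the naming rule, was not among the kept genes and was not analysed here. Features designed on the endogenous transcript detect the construct only as far as the 2 share sequence.

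**Figure D1:**
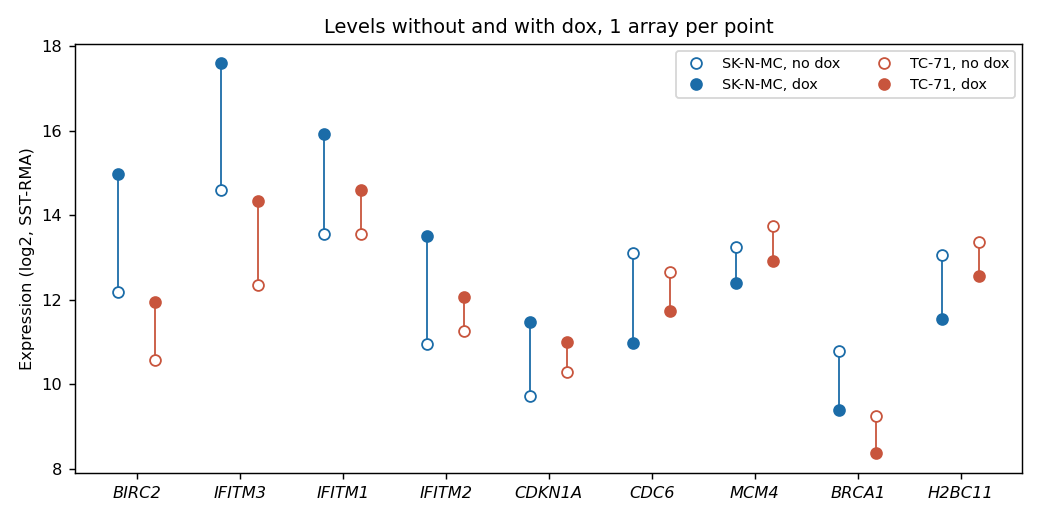
Log2 expression (SST-RMA) of 9 genes, with 1 array per point, open circles without dox and filled circles with dox, and lines joining the arrays of a cell line. BIRC2 and the IFITM genes were higher with dox in both lines, and CDC6, MCM4, BRCA1 and H2BC11 were lower.

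Next, the genes that differed with dox in both lines were examined. IFITM3, a membrane protein that restricts virus entry, had the largest shared increase. It was 7.98-fold higher in SK-N-MC and 3.96-fold higher in TC-71, above the increase of BIRC2 itself. Its family members IFITM1 (5.14-fold and 2.09-fold) and IFITM2 (5.83-fold and 1.76-fold) were also higher in both lines. Further genes with at least a 2-fold increase in both lines were OXR1, an oxidation resistance gene (2.37-fold and 2.53-fold), the mitochondrial nucleotide carrier SLC25A36 (3.08-fold and 2.20-fold) and the vesicular glutamate transporter SLC17A7 (2.20-fold and 2.17-fold). The other genes of the shared increase were LIMCH1, BCAM, TBX3, SAMD13 and the interferon-inducible IFI6, which was 1.77-fold and 1.73-fold higher. Because IFITM1, IFITM2 and IFITM3 are close copies of each other, cross-hybridisation between their features cannot be separated from 3 separate increases.

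Replication and histone genes were among the largest shared decreases. CDC6, a replication licensing factor, was 4.42-fold lower in SK-N-MC and 1.91-fold lower in TC-71. BRCA1, a DNA repair gene, was 2.62-fold and 1.86-fold lower. The helicase subunit MCM4 was 1.78-fold and 1.79-fold lower, and the cell cycle transcription factor E2F1 was 1.98-fold and 1.74-fold lower, with E2F2 beside it. Core histone genes took 5 of the 12 places (H3C15, H3C10, H2BC11, H3C1 and H2BC13), of which H3C15 was 2.94-fold and 1.94-fold lower. The glucose transporter SLC2A1 was 1.80-fold and 1.75-fold lower, and the transcription factor CREB5 was 1.97-fold and 2.19-fold lower. In TC-71 CREB5 went from 6.38 to 5.25, near the low end of the array, so the size of that decrease is uncertain.

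Of 13975 genes, 55 were at least 1.5-fold higher in both lines, where independent lists of the same sizes would share 19.0, and 53 were at least 1.5-fold lower in both, against 17.6. At a 2-fold limit, 6 genes were higher in both lines and 0 were lower in both. Over all genes the differences of the lines were only weakly related (Pearson's r = 0.119, Spearman's rho = 0.0943, across genes, which are not independent replicates). In the test over both lines, IFITM3 alone passed at an adjusted p of 0.0175 (limma), and its mean log2 difference was 2.49 ± 0.25 (moderated SE). No gene passed as lower. At an unadjusted p under 0.05, 454 genes were higher and 459 lower, where 699 in all are given by chance. With 1 residual degree of freedom the call is not firm: IFITM3 had an adjusted p of 0.260 after quantile normalization and 0.139 after median centring and with a log2 difference of at least 2.48 in both. With a prior that follows expression level, 6 genes were called higher and 4 lower, among them IFITM3, BIRC2, IFITM1, CDC6 and H2BC11.

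**Figure D2:**
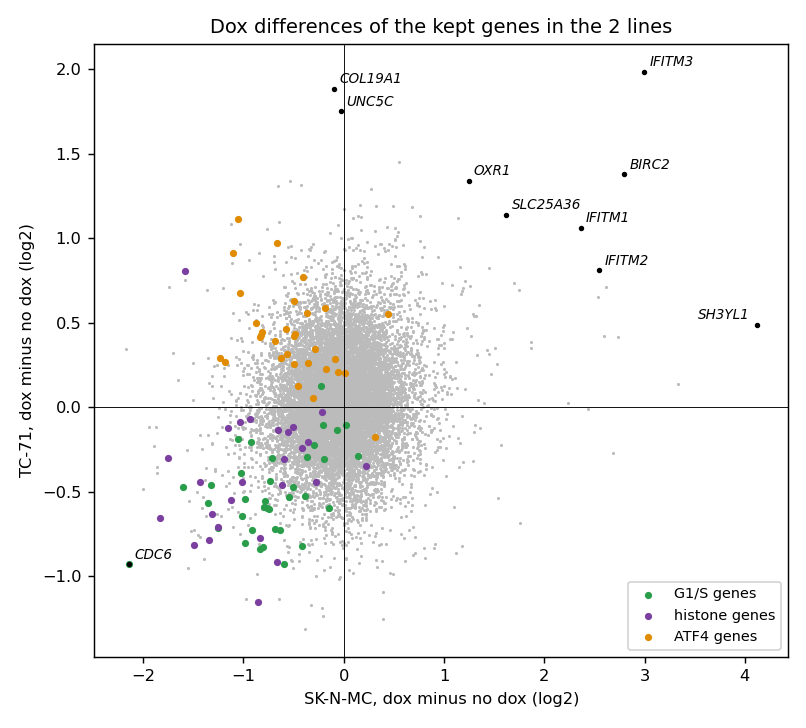
Difference with dox against without dox in SK-N-MC (x axis, log2) and TC-71 (y axis, log2) for 13975 genes in grey, with 3 gene lists in colour and 10 genes named. G1/S and histone genes lie mostly in the lower left, ATF4 genes in the upper left, and BIRC2 and the IFITM genes in the upper right.

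The fixed gene lists showed the same S-phase decrease. Of 36 measured G1/S genes, 33 were lower in both lines. The list median was -0.74 in SK-N-MC and -0.54 in TC-71, below all 10000 random lists matched on expression in each line. No G1/S gene passed the test over all genes, and 27 fell and 0 rose when p was adjusted over the list alone. These included CDC6, the replisome factor CDC45, the checkpoint adaptor CLSPN and the ubiquitin ligase adaptor DTL. Replication-dependent histone genes had medians of -0.90 and -0.39, with 24 of 26 lower in both lines and 13 that fell when adjusted over the list alone, including the linker histone H1-5. Histone genes share sequence, so features of single members are uncertain. Set tests with a preset correlation (camera) gave adjusted p = 3.26e-28 for G1/S genes and 6.47e-22 for histone genes, and adjusted p = 0.989 for each with an estimated correlation. The estimated correlations were 0.0857 for G1/S and 0.458 for histone genes, against the preset 0.01. The small p-values compare genes with genes and do not measure a repeat across the lines.

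The mitotic genes did not move alike in the lines. G2/M genes had a median of -0.39 in SK-N-MC, below all random lists, and 0.02 in TC-71, at the 44.3rd percentile of random lists. KIF11, KIF2C, MKI67 and CDK1 were the members with the largest mean decrease, and 0 members passed either adjustment. The difference between the lines' responses had a median of -0.31 over this list, at the 0.08th percentile of random lists. The camera test over both lines gave an adjusted p of 0.00288 for the G2/M list, and adjusted p = 0.989 with an estimated correlation.

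Among p53 target genes, CDKN1A, the cyclin-dependent kinase inhibitor p21, was 3.35-fold higher in SK-N-MC and 1.62-fold higher in TC-71. It was the single member of 22 that passed when adjusted over the list alone, and its adjusted p over all genes was 0.334 (limma). TP53INP1 was higher in both lines, and AEN and FAS were lower in both. The list median was -0.03 in SK-N-MC and 0.21 in TC-71, at the 56.2nd and 99.5th percentiles of random lists, with a camera adjusted p of 0.778. The TC-71 value lay inside the central 95% with no filter (96.98th percentile) and by the list mean (95.75th).

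Interferon-stimulated genes as a list were called higher by camera (adjusted p = 0.000659, and adjusted p = 0.989 with an estimated correlation). Of 23 measured members, 1 passed over all genes and 5 rose when adjusted over the list alone: IFITM3, IFITM1, BST2, IFI6 and USP18. BST2, the antiviral tetherin, was 2.35-fold higher in SK-N-MC and 1.38-fold in TC-71. The list median was -0.03 in SK-N-MC, at the 47.3rd percentile of random lists, and 0.31 in TC-71, at the 99.98th. In SK-N-MC 12 of the 23 members were lower with dox, including the RNA sensor RIGI. Without IFITM1 and IFITM3, an alternative chosen after seeing the data, the medians were -0.08 and 0.29, and the unadjusted camera p was 0.0110. The SK-N-MC median was 0.03 after median centring, so its sign rests on the scaling. MHC class I presentation genes had medians of -0.12 and 0.14 and a camera adjusted p of 0.709; HLA-C was the member with the largest mean difference, 0.55 and 0.63.

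The pathways in which BIRC2 acts were examined with lists that leave out BIRC2 itself. Of 20 measured genes of the IAP family and TNF receptor complex, of 9 in the non-canonical NF-kB pathway and of 21 TNF and NF-kB target genes, 0 were at least 1.5-fold different in either line. The lists held 30, 23 and 38 genes, and those not among the kept genes, BIRC3 included, were not assessed. The target list had medians of -0.10 in SK-N-MC and -0.08 in TC-71, and its leading members were CXCL8, SOD2, CSF1 and MAP3K8, all between -0.56 and 0.01. The non-canonical list had medians of -0.21 and 0.32, the second at the 98.7th percentile of random lists, and the median of its difference in response between the lines was -0.60, at the 0.25th percentile. The TC-71 value lay inside the central 95% with no filter (median 0.16, 94.04th percentile) and by the list mean (96.74th). Camera adjusted p-values were 0.966, 0.709 and 0.709 for the IAP, non-canonical and target lists. The TC-71 median of the target list was at the 5.09th percentile, and at the 1.07th with no filter. Apoptosis regulators had medians of -0.09 and -0.08, the second at the 2.22nd percentile, at the edge of the central 95%, and an adjusted p of 0.709. Among them FAS and TNFRSF10A, both death receptors, were lower in each line, and the pro-death BAK1 and BMF were higher in each line, with 0 of 26 members past either adjustment.

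**Figure D3:**
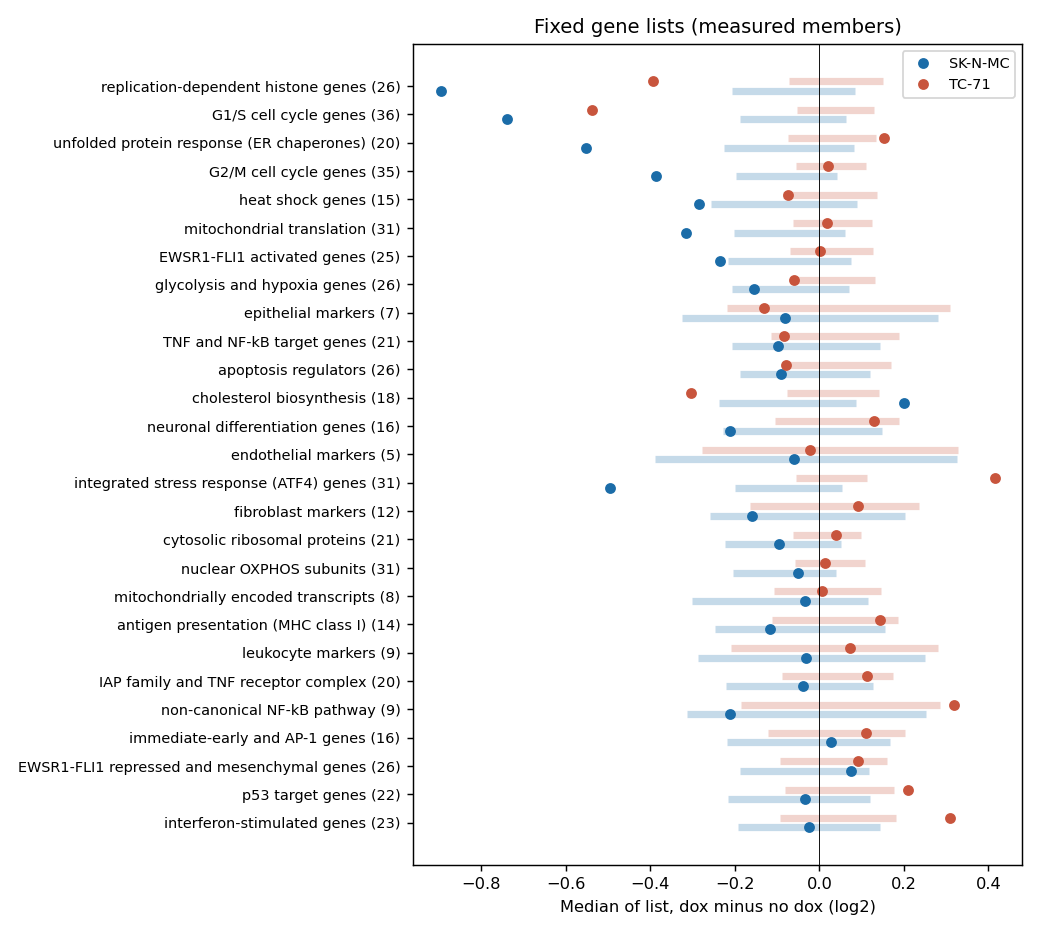
Median log2 difference with dox against without dox of 27 gene lists (points, x axis) in SK-N-MC and TC-71, with pale bars for the central 95% of 10000 random lists matched on expression and the number of measured members in brackets. Histone and G1/S genes lie below the bars in both lines, and ATF4, ER chaperone and cholesterol genes lie outside them on opposite sides.

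The comparison within SK-N-MC gave the wider response. Of 13975 genes, 83 were at least 2-fold higher and 147 at least 2-fold lower with dox. After centring each array on its median the counts were 107 and 108, and after quantile normalization 106 and 122, so the size of the excess of decreases moves with the scaling. The largest increase was in SH3YL1, an SH3 and SYLF domain gene, at 17.4-fold, against a log2 difference of 0.49 in TC-71. The heparan sulfate proteoglycan SDC2 (6.65-fold), FBXL6 (6.43-fold) and the sodium pump subunit ATP1B2 (6.04-fold) were also much higher in SK-N-MC, with log2 differences of 0.42, -0.27 and 0.42 in TC-71. The largest decreases were in MBD3L5, CDC6, the phosphatase PTPN22 (3.85-fold), the lipase ABHD6 (3.72-fold), the motor adaptor HOOK1 (3.66-fold) and MBD3L4. MBD3L4 and MBD3L5 are near-identical copies and are uncertain as single genes. With dox they lay at 5.58 and 5.51 in SK-N-MC, near the low end of the array. The size and rank of their decreases are therefore uncertain too. ER chaperone genes of the unfolded protein response had a median of -0.55, with 10 of 20 at least 1.5-fold lower, among them HERPUD1 (2.49-fold) and HSPA5, the main ER chaperone (2.05-fold). ATF4 target genes of the integrated stress response had a median of -0.50, with 12 of 31 at least 1.5-fold lower, including TRIB3 (2.36-fold) and SESN2 (2.27-fold). Both lists lay below all random lists. EWSR1-FLI1 activated genes had a median of -0.24, at the 1.07th percentile, with VRK1, CCK, MYBL2 and CAV1 as the leading members. Mitochondrial translation genes had a median of -0.31. Heat shock genes had a median of -0.29, at the 1.10th percentile, against -0.07 in TC-71, and a camera adjusted p of 0.256. By the list mean (-0.18) they lay inside the central 95% in SK-N-MC, at the 12.76th percentile. Cholesterol synthesis genes had a median of 0.20, at the 99.93rd percentile.

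Within TC-71, 38 genes were at least 2-fold higher and 12 at least 2-fold lower. After centring each array on its median the counts were 25 and 25, and after quantile normalization 28 and 18, so the size of the excess of increases moves with the scaling. IFITM3 led the increases, followed by the collagen COL19A1 (3.70-fold), the netrin receptor UNC5C (3.37-fold), CFAP221, BIRC2 and OXR1. COL19A1 and UNC5C differed by -0.10 and -0.03 on the log2 scale in SK-N-MC, where both had levels near 5. The largest decreases were in the acyl-CoA thioesterase ACOT1 (2.48-fold), the protease BACE2 (2.39-fold), CCDC40, H3C10, the secretogranin SCG2 (2.20-fold) and CREB5. BACE2 was at 6.05 without and 4.79 with dox, and CREB5 at 5.25 and CCDC40 at 5.80 with dox, near the low end of the array. The size and rank of these decreases are uncertain. ATF4 target genes had a median of 0.41, above all random lists, with 7 of 31 at least 1.5-fold higher and 0 lower. ER chaperone genes had a median of 0.15, which lay inside the central 95% with no filter (96.29th percentile), and cholesterol synthesis genes of -0.30 with 17 of 18 lower. EWSR1-FLI1 activated genes had a median of 0.00 and mitochondrial translation genes of 0.02.

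ATF4, ER chaperone and cholesterol genes were compared between the lines by the median of the difference in response. It was -0.92 for ATF4 genes and -0.84 for ER chaperones, below all random lists, and 0.48 for cholesterol genes, above all random lists. These percentiles describe the 4 arrays and carry no replicate error. In the test over both lines, camera gave ATF4 genes an adjusted p of 0.778 and cholesterol genes 0.709. It called ER chaperones lower at adjusted p = 0.0182, mitochondrial translation genes at 0.0293 and EWSR1-FLI1 activated genes at 0.0425, in which SK-N-MC carried the decrease, and each had adjusted p = 0.989 with an estimated correlation.

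Mitochondrially encoded transcripts (medians -0.03 and 0.01) and nuclear OXPHOS subunits (-0.05 and 0.01) lay inside the range of random lists, as did cytosolic ribosomal protein genes (-0.10 and 0.04). EWSR1-FLI1 repressed and mesenchymal genes had medians of 0.08 and 0.09, a list mean at the 99.74th percentile in SK-N-MC and a camera adjusted p of 0.103, with SPARC 1.47 and 0.20 and ACTA2 0.57 and 0.78 higher on the log2 scale. Glycolysis and hypoxia genes had medians of -0.15 and -0.06, and SLC2A1 was the member that fell when adjusted over the list alone. Immediate-early and AP-1 genes had medians of 0.03 and 0.11 and a median difference in response of -0.41, at the 0.55th percentile of random lists, with MYC 2.19-fold lower in SK-N-MC and 1.06-fold lower in TC-71. Neuronal differentiation genes had medians of -0.21 and 0.13, the second at the 99.66th percentile with no filter, and SCG2 fell when adjusted over the list alone. Markers of other cell types stayed inside the range of random lists in both lines: leukocyte (-0.03 and 0.07), epithelial (-0.08 and -0.13), endothelial (-0.06 and -0.02) and fibroblast (-0.16 and 0.09) medians. AIF1, a leukocyte marker that was 0.54 higher in SK-N-MC and 1.04 higher in TC-71, was the member of these 4 lists that rose when adjusted over its list alone.

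The lines differed from each other far more than either did with dox. Over the 4 arrays, 448 genes were at least 4-fold higher and 497 at least 4-fold lower in SK-N-MC than in TC-71 (limma, adjusted p under 0.05, dox as a term, n = 2 arrays per line). The 2 arrays of a line are 1 without and 1 with dox. These p-values and the SEs below therefore measure no replicate spread within a line. Higher in SK-N-MC were TCEA3, the neural crest transcription factor TFAP2B (8.28 ± 0.19, log2 difference ± moderated SE), GALNT17, the cyclin CCND2 (7.59 ± 0.23), GABRQ, the cyclin-dependent kinase inhibitor CDKN2A (7.49 ± 0.26), CYYR1, TMEM71 and ARHGAP15. CDKN2A was at 4.46 and 3.64 in the TC-71 arrays, below the level of 6.14 that genes had to reach on average. Lower in SK-N-MC were the glutathione transferase MGST1 (-10.38 ± 0.20), the Wnt antagonist DKK2 (-9.39 ± 0.19), S100A11, CPE, the cohesin subunit STAG2 (-8.63 ± 0.19), LMO3 and PCDH10. STAG2 was at 5.97 and 6.27 in the SK-N-MC arrays and at 14.71 and 14.79 in TC-71. DKK2 belongs to the EWSR1-FLI1 activated list, which as a whole had a median line difference of 0.21 and a camera adjusted p of 0.867. Single histone genes were among the differences in either direction, with H2AC8 higher in SK-N-MC by 9.36 ± 0.42 and H4C3 differing by -11.13 ± 0.21, and H2BC12 and H2BC12L also lower. Where the lower line lies near the low end of the array, as for these genes, CDKN2A, MGST1 and STAG2, the size of the difference is uncertain and its rank is not determined.

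The fixed lists showed ER chaperones higher in SK-N-MC, with a median of 1.18 and 11 of 20 genes at least 2-fold higher at an adjusted p under 0.05 (camera adjusted p = 0.00294), DNAJB9 and DERL1 among them. Mitochondrial translation genes were lower (median -0.64, adjusted p = 0.00535), as were histone genes (-0.91, adjusted p = 0.0111) and immediate-early and AP-1 genes (-0.37, adjusted p = 0.0280). Each of these 4 lists had adjusted p = 0.955 with an estimated correlation. The gap depended on the condition: without and with dox its median was 1.73 and 0.64 for ER chaperones, -0.53 and -0.71 for mitochondrial translation, -0.40 and -1.16 for histone genes, and -0.09 and -0.56 for immediate-early and AP-1 genes. These camera p-values set the genes of a list against the other genes. The residual of the fit behind them is the difference between the lines' dox responses. They therefore measure no replicate spread within a line.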

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

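The tests of scaling, of neighbouring genes and of background signal were chosen after the results were seen. None of the differences between the lines below was tested against replicate error, since each line has 1 array per condition, and they are given because the lines moved in opposite directions.

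ATF4 target genes had a median of -0.50 in SK-N-MC and 0.41 in TC-71, ER chaperones -0.55 and 0.15, and cholesterol synthesis genes 0.20 and -0.30. For ATF4 and cholesterol genes, the smallest of their medians in size was 0.26 under quantile normalization or median centring. The deposited values were already normalized and these scalings move all genes little, so these medians could hardly change sign. Their opposite directions do not rest on the choice among these scalings, and whether the authors' normalization shaped them was not tested. For ER chaperones, between-array scaling stays open in TC-71, where the median was 0.0731 after centring. Different starting levels of the lines stay open: the gap between the lines was smaller with dox for 2 of the 3 lists, 0.99 to 0.11 for ATF4 genes and 1.73 to 0.64 for ER chaperones, and went from -0.13 to 0.30 for cholesterol genes. That measure rests on the same arrays as the opposite responses and restates them, so it decides neither way. Differences between single flasks in nutrient or density state stay open too, as there were 0 repeat flasks.

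At least 1.5-fold, 32 genes were lower in SK-N-MC and higher in TC-71, against 32.4 for independent lists, and 17 were higher in SK-N-MC and lower in TC-71, against 10.3. At this limit, genes lower in SK-N-MC are thus no more than chance gives, and the excess in the other direction was not tested. At 2-fold the counts were 2 against 0.400 and 0 against 0.0713, too few to read. Single genes that moved in opposite directions were the acetyl-CoA synthetase ACSS2 (1.11 in SK-N-MC and -0.87 in TC-71, log2), TNNI3K (0.89 and -0.83), KRT12 (1.18 and -0.82) and GABRA2 (0.91 and -0.81). In the other orientation were DPYSL3 (-1.13 and 1.08), the ATF4 targets PCK2 (-1.05 and 1.12) and SLC7A11 (-1.11 and 0.91), and FSIP1 (-1.03 and 0.97). KRT12, GABRA2 and DPYSL3 had levels down to 5.38, 5.68 and 5.09 in TC-71, near the low end of the array.

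In SK-N-MC, 4 of the 6 most increased genes (SH3YL1, SDC2, FBXL6 and ATP1B2) differed by less than 1.5-fold in TC-71. Their lowest level with dox was 9.10, against a median of 6.84 over all features. The genes were picked for a large increase among genes past a level filter, which by itself favours a high level with dox. That level therefore does not decide whether signal near background was the source of the increase. Background also stays open for the size of the increase of ATP1B2, at 6.50 without dox. The same holds for the small differences of SDC2, FBXL6 and ATP1B2 in TC-71, where the lowest level was 6.03. For transcription spreading from an insertion site of the construct, the 7 directly adjacent kept genes were examined. They differed by -0.55 to 0.39, below 1.5-fold, so no spread to those genes was seen. Genes below the level filter were left out, which can remove silent neighbours, and ACP1 was the only neighbour examined for SH3YL1. Spreading to genes outside the 7 therefore stays open. The test of adjacent genes was set anew after a first form, over the 6 most increased genes, gave 1 with a neighbour at least 1.5-fold higher (IFITM3, beside IFITM1), within the 95th percentile of 2 in random draws. An insertion that affects a single gene, selection of a subpopulation, and a response that only SK-N-MC makes remain open and were not tested.

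Among features outside the named genes, with several symbols or none, 778 passed the level filter. Of these, 4 were at least 1.5-fold higher and 2 at least 1.5-fold lower with dox in both lines. The largest, without a gene name in the table used, was 2.44 and 1.54 higher on the log2 scale.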

How the results depend on the processing

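All alternatives here were planned, except leaving IFITM1 and IFITM3 out of the interferon list. The increase of BIRC2 kept its direction and size in both lines under quantile normalization and median centring, and averaging of features left it unchanged. No named gene or list that was called reversed under an alternative. Among the values for single genes and lists, 958 kept their side of the threshold, while 18 lost a call and 18 gained one. Of the 958, 38 had the other sign, all of them list medians inside the central 95% of random lists or camera directions past no threshold. Many gene values could not reverse: the filters leave a gene's difference as it is. The other priors and the fit without the cell line term leave the mean difference as it is. For those values the absence of a reversal carries no information. The test over both lines called 1 gene higher and 0 lower as deposited. It called 0 higher after quantile normalization, after median centring and with the filter on the highest array, where IFITM3 had adjusted p-values of 0.260, 0.139 and 0.0551 (limma) with a log2 difference of at least 2.48. It called 4 higher with no filter, and 6 higher and 4 lower with an expression-dependent prior. Without the cell line term ("no replicate block", where the paired design by cell line is dropped), 0 genes were called higher and IFITM3 had an adjusted p of 1.00, because the lines' own levels then enter the spread. Over all alternatives its adjusted p ran from 9.74e-06 to 1.00. The cause of the other changes in the count was not tested. In SK-N-MC the counts of 83 higher and 147 lower genes became 522 and 890 at a 1.5-fold limit, and 19 and 15 at 3-fold. In TC-71 the counts of 38 and 12 became 508 and 276 at 1.5-fold, 4 and 0 at 3-fold, and 25 and 25 after median centring, while 40 were lower with no filter, as more dim genes entered. Genes shared between the lines went from 55 and 53 to 6 higher and 0 lower at 2-fold. Line differences went from 448 and 497 genes to 1727 and 1689 at 2-fold. The correlation of the dox differences of the 2 lines across genes was 0.0577 with no filter and 0.130 with the filter on the highest array. Camera called 1 list higher and 6 lower, against 0 and 0 with an estimated correlation, and 2 higher with the filter on the highest array, where the EWSR1-FLI1 repressed list was added. The EWSR1-FLI1 activated list had an adjusted p of 0.0900 after quantile normalization. The interferon list's mean in SK-N-MC was 0.26, against a median of -0.03, as IFITM1 and IFITM3 carry it. The scalings moved the median of all genes from -0.04 to 0.00 and 0.01 in SK-N-MC, and from 0.03 to 0.00 and -0.04 in TC-71. Averaging the features of a gene affected 1 symbol. Leaving out a line leaves no residual degree of freedom, and the values of each line alone stand in the report. Near the low end of the array, where signal over background is small, differences of single genes are least precise.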

Other observations

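The scaling test was chosen after its result was seen, and the 2 added gene lists were written after other results had been seen.

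Most genes of an added DNA repair list were also lower in both lines. After BRCA1 was seen among the shared decreases, a list of homologous recombination and Fanconi genes that leaves out BRCA1 and EXO1 was examined. Of its 23 measured members, 19 were lower in both lines, with medians of -0.36 in SK-N-MC and -0.24 in TC-71. XRCC2, a homologous recombination gene, differed by -1.38 and -0.65, the helicase BLM by -0.92 and -0.46, and the polymerase POLQ by -0.61 and -0.65. These 3 were among the 4 members that fell when adjusted over the list alone (limma), a list chosen after the data were seen. TXNIP, a glucose-responsive regulator, was 1.19 higher in TC-71 and 0.49 in SK-N-MC.

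G1/S and histone genes were lower with dox in both lines. The TC-71 median of the G1/S list was -0.58 or lower under both other scalings. The deposited values were already normalized, and these scalings moved the TC-71 median of all genes only from 0.03 to 0.00 and -0.04. They could thus hardly bring the list near 0. The decrease does not rest on the choice among these scalings, and whether the authors' normalization shaped it was not tested. The prediction of a wider fall of S-phase expression held for the repair list, whose higher percentile of the 2 lines was 0.05 among random lists. Those random lists were matched on level only. The percentile therefore does not separate a fall of repair genes from the fall of the G1/S genes. Exit into a quiescent state was tested with a list that leaves out YPEL3 and TXNIP. Its lower percentile was 84.24, in SK-N-MC, short of the upper limit of the central 95% that was set beforehand. By that rule the outcome counted against a quiescent exit shared by both lines. The SK-N-MC median was 0.06 with 8 members higher and 7 lower, which was read, only after it was seen, as deciding neither way. In TC-71 the median was 0.27, at the 99.8th percentile, with 12 of 15 members higher. G2/M genes, however, had a median of -0.39 in SK-N-MC and 0.02 in TC-71. Whether the pattern is a response to BIRC2 or to dox itself cannot be told apart, as 0 arrays came from dox-treated cells without the construct.

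Single histone genes differed between the lines in opposite directions. H4C3 was at 4.63 and 4.85 in SK-N-MC and 16.04 and 15.69 in TC-71, and H2AC8 at 14.93 and 13.34 in SK-N-MC and 4.38 and 5.18 in TC-71.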
